A study of Homo sapiens with 30 samples.

How the data were processed

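RNA of human effector memory T cells was measured in 30 libraries, 3 in each of 10 groups given by the labels: CD4 and CD8 cells of blood, and the CD69- and CD69+ fractions of CD4 and CD8 cells of spleen and lung. Per the labels' protocols, tissue was digested with enzymes and by mechanical means, blood was separated on density medium, cells were sorted, and libraries were made with a TruSeq kit after poly-A selection. Per the submitters' processing notes, reads were processed with TopHat, HTSeq and DESeq2 on the hg19 build, versions not given, and whether counting used strand is not given in the sources used here. The authors deposited a table of read counts per gene symbol, whole numbers that were not normalized, and a normalized signal table of the same genes. The deposited signal values were those counts divided by DESeq2 size factors: multiplied back, 100% of them were whole within 0.001 reads and equal to the count table, so every test used the counts and the normalized table added no separate result. Both tables held 25559 symbols, 0 rows without a gene name and 0 columns that matched no sample. No donor, date or batch was tied to a library.

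Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the quasi-likelihood F test with TMM scaling, after filterByExpr with a minimum count of 10. Each lineage was fitted on its 15 libraries as 5 groups that share an estimate of the spread. CD8 and CD4 cells were compared, and differences averaged over both, in a fit of all 30 libraries. The fits tested 16022, 15762 and 16918 genes for CD4, CD8 and all libraries, at common biological coefficients of variation of 0.485, 0.46 and 0.486. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Standard errors are the log2 fold change divided by the square root of F, so they follow from the test. CPM values are counts per 1e6 of each library's total, given as mean ± SD. Gene lists, 28 in number and covering T cell programs, stress, metabolism and markers of other cells, were fixed before the data were examined. Some genes sit on several lists, so tests of different lists are not independent. The follicular helper list shares CXCL13, IL21, PDCD1, BTLA, ICOS, MAF and CXCR5 with other lists and holds POU2AF1, also a gene of B cells. Each list with at least 3 tested members, except the 5 genes of the label check, was counted over all genes and adjusted over the list alone, and tested with limma's camera at a preset inter-gene correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. One list, of mitochondrially encoded genes, had 0 of its members in the table. Over the comparisons planned in advance, the averages left out, 227 of 494 list tests passed with the preset correlation and 65 with the estimated one.

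Genes were named by a rule fixed before the data were examined. For CD69+ against CD69- cells, and for genes shared between tissues, these were the 8 called genes of largest rise and the 8 of largest fall by fitted fold change, among genes whose libraries separated completely and whose higher group averaged at least 5 CPM. For other comparisons they were the 5 of each, and called members of the lists were added as examples. For differences averaged over tissues or lineages the rule was adapted to require that the group means move the same way in every pair. Sex-linked genes, immunoglobulin and T cell receptor segments and genes of common deletion or splice polymorphisms were not named, and some genes that met the rule are not reported here. CXCR6 in lung CD4 cells and S1PR1 where it was not called were chosen after their values were seen. So were ZNF683 for the lung minus spleen difference and in spleen CD8 cells, and the CPM ranges of FOS, MALAT1, RN7SK, SFTPC and CD79A. Near-identical copies and antisense genes are reported as uncertain. Gene positions and strand overlaps of other genes were not checked. Where a group had 0 counts of a gene, the fold was set against 3 counts over the group's summed libraries, and with 1 to 3 counts an exact conditional 95% interval of the ratio of counts is given.

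Alternatives fixed in advance were DESeq2 1.42.0 with its size factors, its size factors within edgeR, no filter on low counts, 1 fit of all 30 libraries, 2 surrogate variables (sva 3.50.0), and leaving out each library of a comparison in turn. A block for donors was planned only if the columns gave them, which they did not. Chosen after seeing the data were the differences averaged over tissues and lineages, leaving out the 4 spleen libraries of low immediate early RNA, and leaving out 2 shallow tissue libraries (spleen CD4 CD69- replicate 3 and lung CD8 CD69+ replicate 1). Other splits of the libraries were run as the 10 splits of 3 against 3, or as 100 drawn regroupings. Genes called in both tissues were set beside the number that independent lists would share.

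The tests were tried on simulated counts with the real means and totals and known fold changes. edgeR found 0%, 24.2% and 78.5% of genes changed 2-, 4- and 8-fold in the design of CD69+ against CD69- spleen CD4 cells, with 3 false calls among 15455 unchanged genes. It found 3.12%, 36.9% and 63.5% in that of lung CD8 cells (5 false calls), 0%, 22.7% and 69.7% in that of CD69- spleen against blood CD4 cells (1), and 1.56%, 51.5% and 64.6% in that of lung against spleen CD69+ CD8 cells (0). For the CD4 difference between tissues it found 0%, 1.56% and 26.2% (0), and for the average over tissues and lineages 47.8%, 81.5% and 96.9% (7).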

Results

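Memory T cells circulate through blood or stay in tissues, and CD69, a surface protein that pulls the egress receptor S1PR1 off the membrane, is widely used to mark cells that stay. RNA was sequenced from 30 libraries of human effector memory T cells, defined by surface CD3 without CD45RA or CCR7 and sorted as CD4 or CD8 cells from blood, spleen and lung. Spleen and lung cells were sorted further into CD69+ and CD69- fractions, and the blood cells were CD69- by the series design, although the label of blood CD4 replicate 2 carried no CD69 entry. Each of the 10 groups held 3 libraries. The tissues came from 3 organ donors, but no label tied a library to a donor, so donors could not be modelled and p-values measure the spread between libraries, some of which share a donor. Tissue was digested and blood was separated on density medium, so blood differed from tissue in handling, and possibly in donors, as well as in site.

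The deposited table held whole read counts for 25559 gene symbols. Totals per library ranged from 2.58e6 to 2.2e7 counts. They ran from 4.17e6 to 7.78e6 in blood (n = 6), 4.54e6 to 2.2e7 in spleen (n = 12) and 2.58e6 to 1.94e7 in lung (n = 12). A count of 10 stood for 3.88 counts per 1e6 of the total (CPM) in the library of lowest total and 0.456 CPM in that of highest total. The 30 pairs of libraries within groups differed by 27.8 to 365 times the counting noise (chi-square per degree of freedom), so none was treated as a copy of another. Unless stated otherwise, changes are log2 fold changes ± standard error of the first-named group over the second, with n = 3 libraries per group and Benjamini-Hochberg adjusted p-values of edgeR's quasi-likelihood test.

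The sorted lineages carried their defining transcripts. CD4 RNA was 176 to 623 CPM in the 15 CD4 libraries against 3.19 to 84.5 CPM in the 15 CD8 libraries, CD8A was 509 to 2460 against 15.2 to 152 CPM, and CD8B was 79.1 to 315 against 0.621 to 15 CPM. CD3E, a chain of the T cell receptor complex, was 367 to 927 CPM in all 30 libraries. S1PR1 RNA separated the CD69 fractions completely, with all 3 CD69+ libraries under all 3 CD69- libraries in 4 of 4 tissue and lineage pairs, an order that chance gives in 5% of pairs. CD69 RNA itself separated them in 0 of 4 pairs, and its averaged difference was 0.89 ± 0.58 (edgeR adjusted p = 0.887; 0.45 to 1 over the alternatives tried). In 4 of the 12 spleen libraries, replicate 1 of each spleen group, the immediate early gene FOS lay between 11.5 and 14.3 CPM against 2030 to 4070 CPM in the other 8. In the same libraries CD69 RNA lay between 143 and 218 CPM against 1770 to 10700 CPM.

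**Figure D1:**
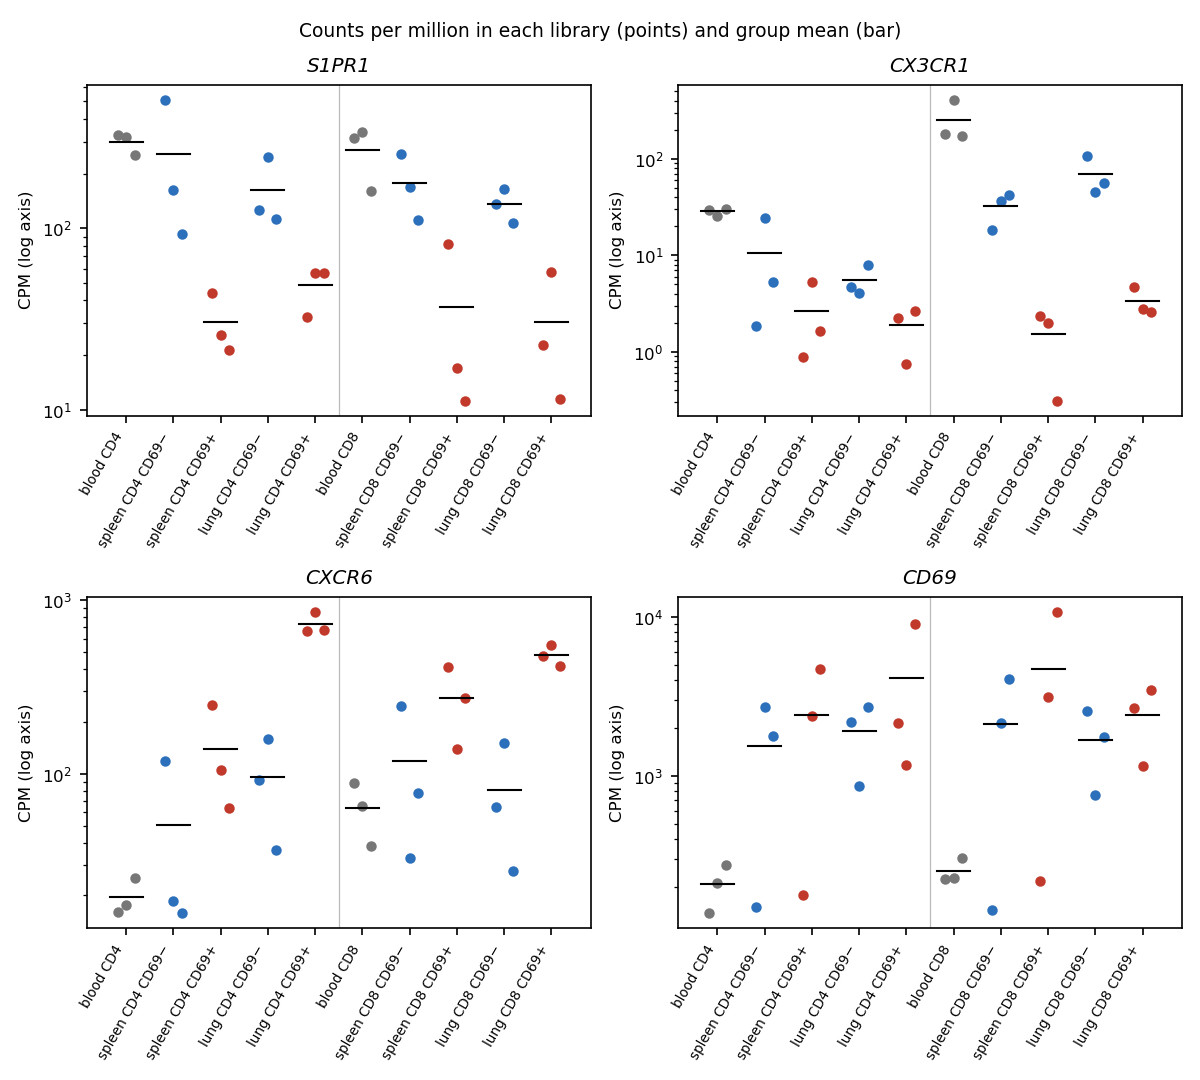
CPM (log axis) of S1PR1, CX3CR1, CXCR6 and CD69 in each of the 30 libraries (points), with the mean of each group of 3 (bars), for blood and for the CD69- and CD69+ fractions of spleen and lung in CD4 and CD8 cells. S1PR1 lies lower in all 3 CD69+ than in all 3 CD69- libraries in 4 of 4 pairs, whereas CD69 RNA separates the fractions in 0 of 4.

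Within each tissue, the comparison of CD69+ with CD69- cells asks which genes go with the residency marker. In spleen CD4 cells, S1PR1, the receptor through which lymphocytes follow sphingosine-1-phosphate out of tissue, had 30.4 ± 12 CPM in CD69+ against 256 ± 224 CPM in CD69- cells (SD, n = 3 each) and fell by 3.12 ± 0.50 on the log2 scale (adjusted p = 0.027). The ephrin receptor EPHA4 (-2.90 ± 0.42), the tetraspanins TSPAN18 (-3.19 ± 0.48) and TSPAN2 (-2.96 ± 0.43), the endosomal protein gene D4S234E (now NSG1; -2.67 ± 0.41) and the organic anion transporter SLCO3A1 (-1.82 ± 0.27) fell as well (adjusted p = 0.0224 to 0.0237). GAS6, a ligand of the TAM receptor kinases, rose by 2.55 ± 0.33 (adjusted p = 0.0223), CDK5R1, an activator of the kinase CDK5, by 2.42 ± 0.38 (0.0269) and FLT4, a receptor for vascular endothelial growth factors, by 2.33 ± 0.38 (0.0301). These 9 of 16022 genes passed, 3 higher and 6 lower, and in each all 3 libraries of 1 fraction lay above all 3 of the other. Of the 15 egress and recirculation genes tested, 1 fell across all genes and 5 when adjusted over the list alone, and the list was lower as a set (camera adjusted p = 3.13e-12; 0.000833 with an estimated correlation). None of the 12 follicular helper genes passed across all genes, but 5 rose when adjusted over the list alone and the list was higher (1.02e-11; 0.000505 with an estimated correlation). The cytokine and chemokine list was higher with the preset correlation (0.000551; adjusted p = 0.0514 with an estimated correlation), with 3 of 26 members higher when adjusted over the list alone. DESeq2 called 91 genes, 31 higher and 60 lower. The count fell to 0 without CD69- replicate 1, CD69+ replicate 1 or CD69- replicate 2, to 1 without CD69+ replicate 2 and to 3 without CD69+ replicate 3, and rose to 16 without CD69- replicate 3. Without the 4 spleen libraries of low FOS it was 0, with adjusted p-values of the 9 genes of 0.214 to 0.31, and over all alternatives the highest was 0.369 (GAS6).

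In lung CD4 cells, the set of retention and adhesion genes was higher in CD69+ cells and the egress set was lower. Both had a camera adjusted p of 1.08e-07 (0.00398 with an estimated correlation), with 4 of 15 retention genes higher and 3 of 15 egress genes lower when adjusted over each list alone. The cytokine and chemokine set (3 of 26 higher when adjusted over the list alone) and the follicular helper set (0 of 12) were higher too, at adjusted p = 1.21e-10 and 0.0046 (0.00275 and 0.0405 with an estimated correlation). CXCR6, a receptor for the tissue chemokine CXCL16, averaged 733 ± 108 CPM in CD69+ and 95.5 ± 61.0 CPM in CD69- cells (SD, n = 3 each), and S1PR1 48.5 ± 13.9 against 161 ± 73.6 CPM. No single gene passed. edgeR gave 0 calls, with a smallest adjusted p of 0.301. At an unadjusted p under 0.05 it had 512 of 16022 genes, fewer than the 801 of evenly spread p-values. Spread between donors, which was not modelled, can lower such a count, so it does not show that no gene differs. DESeq2 called 26, 8 higher and 18 lower. For S1PR1 the change was -1.70 ± 0.47 (adjusted p = 1; 0.101 to 1 over the alternatives).

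In CD8 cells, CX3CR1, the fractalkine receptor of circulating cytotoxic effector cells, fell in CD69+ cells in both tissues. It averaged 1.53 ± 1.07 CPM in CD69+ against 32.5 ± 12.4 CPM in CD69- spleen cells, a change of -4.39 ± 0.58 (adjusted p = 0.0364). In lung it averaged 3.35 ± 1.13 against 69.5 ± 33.2 CPM, a change of -4.35 ± 0.59 (adjusted p = 0.0404). In lung, PLAC8, a small protein linked to lymphoid cell differentiation, fell by 1.85 ± 0.26 (0.0404), and TMEM200A, a transmembrane protein, rose by 3.32 ± 0.49 (0.0414). S1PR1 averaged 36.6 ± 39.1 against 178 ± 72.9 CPM in spleen and 30.5 ± 23.9 against 136 ± 29.4 CPM in lung (SD, n = 3 each), with adjusted p = 1 and 0.684 (0.0562 to 1 and 0.0913 to 1 over the alternatives). The egress set was lower in both tissues, with 1 of 15 genes lower across all genes and 6 in spleen and 5 in lung when adjusted over the list alone (camera adjusted p = 1.62e-22 and 5.06e-17; 0.00111 and 0.000751 with an estimated correlation). The cytokine and chemokine set, with 23 genes tested, was higher in both (9e-11 and 2.14e-11; 0.00226 and 0.000751 with an estimated correlation), as was the follicular helper set (4.89e-07 and 0.000556; 0.00226 and 0.012 with an estimated correlation). In lung, 3 of 15 retention genes, 2 of 24 residency and effector transcription factors, 1 of 14 inhibitory receptors and 1 of 23 MAPK and T cell receptor feedback regulators rose when adjusted over each list alone. The 4 sets were higher (6.79e-09, 2.03e-05, 0.000914 and 9.42e-08; 0.000751, 0.00293, 0.0123 and 0.02 with an estimated correlation), as was the co-stimulation set (0.000117; 0.00995), with 0 of 16 genes passing over the list alone. Of 26 lists, 14 in spleen and 15 in lung passed with the preset correlation and 3 and 8 with an estimated one. Macrophage and mast cell marker sets were higher in CD69+ spleen cells with the preset correlation only (0.0335 and 0.0414; adjusted p = 0.739 and 0.454 with an estimated correlation).

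Those were the only calls among 15762 genes, 1 in spleen and 3 in lung. At an unadjusted p under 0.05 there were 280 and 569 genes, fewer than the 788 of evenly spread p-values, with the same limit as in lung CD4 cells. DESeq2 called 30 and 85, and in lung its 85 divided into 43 higher and 42 lower against 1 higher and 2 lower by edgeR. Without the 4 spleen libraries of low FOS the edgeR counts were 0 and 0, and over all alternatives CX3CR1 ranged from an adjusted p of 6.11e-12 to 0.339 in spleen and 3.19e-11 to 0.384 in lung. The upper values are those without spleen CD69+ replicate 2 and lung CD69+ replicate 3. The spleen count was 3 without CD69- replicate 1, 1 without CD69+ replicate 1 and 0 without CD69- replicates 2 or 3 or CD69+ replicates 2 or 3, and the lung count was 5 without CD69- replicate 2 and 0 without any other single library. CX3CR1 itself passed in 1 of the 6 fits in each tissue.

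Genes that moved with CD69 in both tissues were counted next. In CD8 cells CX3CR1 passed in spleen and in lung, 1 shared gene against 0.000127 for independent lists. The lists are not independent, since the tissues shared a fit and may share donors, so that number does not weigh the overlap. CX3CR1 also fell in CD69+ cells against blood, at -7.16 ± 0.65 in spleen and -6.02 ± 0.63 in lung, but these comparisons reuse the CD69+ libraries and are no separate support. DESeq2 gave 11 shared genes in CD8 cells and, counted over both lineages, 19 also differing from blood. In CD4 cells edgeR gave 0 shared genes and DESeq2 9, all lower. At an unadjusted edgeR p under 0.05 in both tissues 42 genes were higher, 84 lower and 7 opposite (5.56, 4.79 and 10.9 for independent lists). The CD8 count was 1 without spleen CD8 CD69- replicate 1 or lung CD8 CD69- replicate 2 and 0 without any other single library. In 20 simulations that drew all groups of a lineage, blood included, from the same means, the highest number of shared calls was 0. They held no changed gene and no donors shared between tissues, so a count near 0 was fixed in advance and cannot weigh the overlap.

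The size of the CD69 difference was compared between lung and spleen and between CD8 and CD4 cells. ZNF683, which encodes the residency regulator Hobit, had a lung minus spleen difference of 4.01 in CD8 cells (adjusted p = 1; 0.0135 to 1 over the alternatives). Most of it came from spleen, where ZNF683 was lower in CD69+ than in CD69- CD8 cells (-2.56 ± 0.59, edgeR adjusted p = 0.595). No gene passed by edgeR for lung minus spleen in CD4 cells, lung minus spleen in CD8 cells or CD8 minus CD4 cells, at smallest adjusted p-values of 0.441, 1 and 0.295. Unadjusted p-values under 0.05 numbered 301, 148 and 220, fewer than the 801, 788 and 846 of evenly spread p-values, counts that unmodelled donors can lower. DESeq2 called 11, 1 and 1. As sets, the retention genes and the residency transcription factors had a more positive CD69 difference in lung than in spleen CD8 cells (camera adjusted p = 0.000557 and 6.29e-05; 0.0213 and 0.0126 with an estimated correlation). Without the 4 spleen libraries of low FOS neither set passed with an estimated correlation (adjusted p = 0.0596 for both).

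Because single tissues gave few calls, the 4 CD69 differences were also averaged, a comparison chosen after the single-tissue results were seen. The averaged CD69+ cells had more of the cytokines IL17A (3.38 ± 0.73), IL2 (3.27 ± 0.53), IL21 (2.19 ± 0.44) and IL10 (2.26 ± 0.31) and of CXCL13, the chemokine that draws B cells into follicles (3.04 ± 0.58). They had more ITGA1 (2.50 ± 0.43) and ITGAE (1.46 ± 0.30), integrin chains that bind collagen and epithelial E-cadherin, more CXCR6 (2.09 ± 0.35) and more RGS1, which dampens chemokine receptor signalling (1.61 ± 0.39). They had less CX3CR1 (-3.10 ± 0.38), S1PR1 (-2.30 ± 0.30), FAM65B (now RIPOR2; -1.41 ± 0.21), KLF2, an activator of S1PR1 (-1.80 ± 0.38), and its relative KLF3 (-1.41 ± 0.14). Adjusted p-values of these genes ran from 3.78e-06 (KLF3) to 0.0323 (RGS1). Among the other genes of largest change, GSG2, the histone H3 kinase haspin (2.32 ± 0.47), and SRGAP3, a regulator of Rac signalling (2.06 ± 0.40), rose. Reads of GSG2 were not checked for overlap with ITGAE, which rose too. FGFBP2, a secreted protein of cytotoxic lymphocytes (-3.71 ± 0.67), PTGDS, the prostaglandin D2 synthase (-3.41 ± 0.64), the protease PRSS23 (-2.84 ± 0.51) and the ligand WNT7A (-2.84 ± 0.39) fell. So did RAP1GAP2, which switches off Rap1 (-2.82 ± 0.44), the kinase NUAK1 (-2.76 ± 0.65) and the keratin KRT72 (-2.75 ± 0.56), at adjusted p-values of 0.000162 (WNT7A) to 0.0275 (NUAK1). Group means moved in the stated direction in 4 of 4 pairs for every gene named from this comparison except RBPJ (3 of 4).

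By list, 6 of 15 egress genes fell and 9 when adjusted over the list alone (camera adjusted p = 8.33e-27; 8.39e-07 with an estimated correlation). Of 26 cytokines and chemokines 6 rose, 11 when adjusted over the list alone (4.14e-17; 8.39e-07), among them XCL1 (1.56 ± 0.34), whose reads are uncertain because XCL2 is a near-identical copy. Of 12 follicular helper genes 4 rose and 6 over the list alone (1.15e-11; 2.83e-06), including TOX2 (1.74 ± 0.36) and the co-stimulator ICOS (0.97 ± 0.23). Of 15 retention genes 4 rose and 1, the integrin chain ITGB1 (-0.97 ± 0.21), fell, or 7 and 2 when adjusted over the list alone (2.3e-07; 6.62e-05). The inhibitory receptors CTLA4 (1.0 ± 0.22) and CD96 (0.69 ± 0.17) rose, 2 of 14, and 3 over the list alone (0.000141; 0.00215). IRF4 (1.13 ± 0.26), TOX (0.82 ± 0.20) and RBPJ (0.76 ± 0.17), factors of activated and exhausted T cells and of Notch signalling, rose. TCF7, a factor of naive and central memory cells (-0.69 ± 0.14), fell. Of the 24 transcription factors 6 were higher and 2 lower over the list alone (0.00106; 0.00315). SPRY1 (1.86 ± 0.34) and DUSP6 (1.30 ± 0.33), which restrain MAPK signalling, were the 2 of 23 feedback regulators that rose, with 7 over the list alone (1.42e-07; 0.00886). In each bracket the second p is the one with an estimated correlation. The co-stimulation set was higher (0.00693; 0.0149), with 1 of 16 genes rising and 2 over the list alone. With the preset correlation only, the T helper 17 set (3.59e-05; adjusted p = 0.141 with an estimated correlation) and the chemokine receptor set (0.0423; adjusted p = 0.273) were higher and the proliferation set lower (0.00334; adjusted p = 0.532).

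The averaged comparison called 218 of 16918 genes, 76 higher and 142 lower, of which 54 and 101 changed at least 2-fold, and DESeq2 called 389, sharing 217. Without lung CD4 CD69- replicate 3 the count was 145, and without spleen CD8 CD69- replicate 1 it was 229, the highest of 24 such counts. Of 35 named genes 25 passed in each of the 24 fits without 1 library. DUSP6 passed in 4 of them, RGS1 in 8, TOX in 8, CD96 in 10, NUAK1 in 12, ICOS in 19, IL17A in 22, RBPJ in 22, IL21 in 23 and IRF4 in 23. The highest adjusted p among losses was 0.233, for NUAK1 without spleen CD4 CD69- replicate 2. IL17A, CD96, ICOS, TOX, IRF4, RBPJ, DUSP6, KLF2 and ITGB1 lost their call under at least 1 other setting, at adjusted p-values of up to 0.184, 0.104, 0.0641, 0.0635, 0.0801, 0.0647, 0.098, 0.051 and 0.0573.

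**Figure D2:**
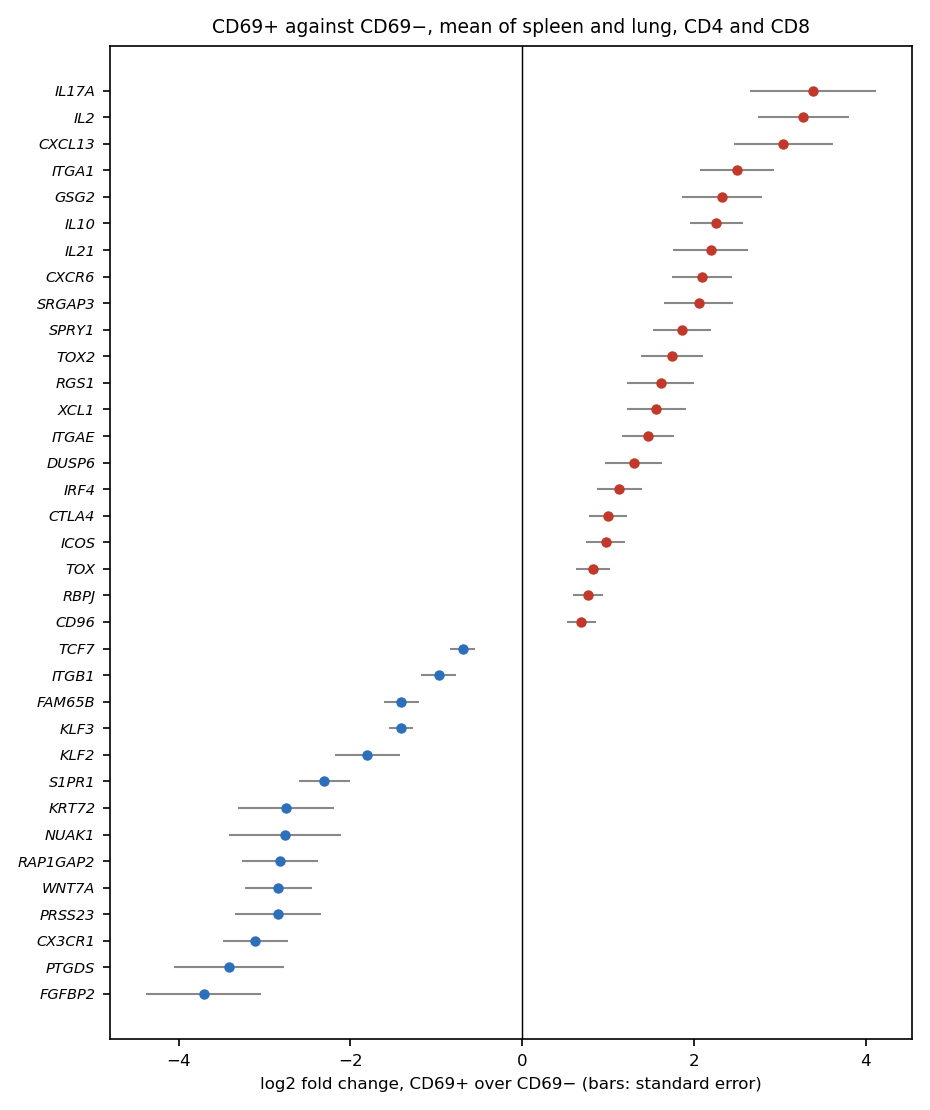
Log2 fold changes of CD69+ over CD69- cells (points, horizontal axis) with standard errors (bars) for the 35 genes named from the comparison averaged over spleen and lung and over CD4 and CD8 cells, from the fit of 30 libraries. IL17A (3.38) and IL2 (3.27) lie at the upper end and FGFBP2 (-3.71) and PTGDS (-3.41) at the lower end.

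Averaged within each lineage, a choice also made after the single-tissue results, CD4 cells had 32 calls (6 higher and 26 lower) and CD8 cells 17 (4 higher and 13 lower). In CD4 cells IL2 (3.28 ± 0.55), the cadherin-like CDHR1 (2.75 ± 0.48), the potassium channel KCNK5 (2.33 ± 0.44), SMAD1 of the BMP pathway (2.22 ± 0.41), CDK5R1 (1.53 ± 0.26) and GAS6 (1.30 ± 0.23) rose. PI16 (-3.10 ± 0.54), FUT7, the fucosyltransferase that makes selectin ligands (-2.99 ± 0.46), the factor SOX13 (-2.88 ± 0.46), WNT7A (-2.73 ± 0.43), KCTD15 (-2.72 ± 0.41), TSPAN18 (-2.62 ± 0.33), S1PR1 (-2.41 ± 0.34), EPHA4 (-2.07 ± 0.29) and KLF3 (-1.44 ± 0.20) fell. In CD8 cells TMEM200A (2.26 ± 0.34), IL10 (1.98 ± 0.30) and PELO, a ribosome rescue factor (1.5 ± 0.24), rose. Reads of PELO were not checked for overlap with ITGA1. FGFBP2 (-4.62 ± 0.67), CX3CR1 (-4.37 ± 0.41), PRSS23 (-3.85 ± 0.54), SOX13 (-2.32 ± 0.40), the acyltransferase AGPAT4 (-1.97 ± 0.28), NHSL2 (-1.64 ± 0.28), the adhesion protein vinculin, VCL (-1.5 ± 0.26), and KLF3 (-1.37 ± 0.20) fell. SMAD1 and GAS6 separated the libraries completely in 1 of 2 tissues, and GAS6 had a lung minus spleen difference of -2.49 ± 0.45 (adjusted p = 0.441), so its average comes mainly from spleen. Adjusted p-values ran from 0.00653 (TSPAN18) to 0.0447 (KCNK5) in CD4 cells and from 0.000581 (CX3CR1) to 0.0398 (NHSL2) in CD8 cells. DESeq2 called 138 genes in CD4 cells, 42 higher and 96 lower, and 122 in CD8 cells. The CD4 count fell to 14 and 12 without lung CD69- or CD69+ replicate 1, to 20 without spleen CD69- replicate 2, spleen CD69+ replicates 2 or 3 or lung CD69- replicate 2, and to 17 without lung CD69- replicate 3. In these cells 5 of the 15 named genes kept their call in all 12 fits (highest adjusted p 0.133, without lung CD4 CD69- replicate 3). The CD8 count was 39 without spleen CD69- replicate 1 or lung CD69- replicate 2. It was 9, 8 and 8 without spleen CD69- replicate 2 or lung CD69- replicates 1 or 3, 5 and 3 without spleen CD69- replicate 3 or CD69+ replicate 2, and 1 without lung CD69+ replicates 1 or 3 or spleen CD69+ replicate 3. CX3CR1 alone of 11 named genes passed in all 12 fits.

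Tissue cells were then set against blood, first for the CD69- fraction, which asks what differs with the site apart from the CD69 gate. Everything in these comparisons also carries the difference in handling, and any difference in RNA of other cells. The nuclear RNA MALAT1 lay at 22800 to 37300 CPM in the 6 blood libraries against 538 to 3740 CPM in the 24 tissue libraries. In CD4 cells, RGS1 rose in spleen and lung CD69- cells by 3.25 ± 0.77 and 4.63 ± 0.82, the activation-linked AP-1 factor BATF by 4.15 ± 0.64 and 3.94 ± 0.63, and the co-stimulator TNFRSF18 (GITR) by 3.88 ± 0.53 and 3.93 ± 0.53. IL10 (3.41 ± 0.91 and 5.42 ± 0.91), CCL3, a chemokine for monocytes and T cells (7.01 ± 0.95 and 6.33 ± 0.93), ITGAE (2.22 ± 0.47 and 1.93 ± 0.47) and the immediate early factor JUN (5.88 ± 1.35 and 6.17 ± 1.37) rose in both as well. TCF7 fell by 1.72 ± 0.32 in lung. Adjusted p-values of these genes were 0.0011 to 0.0238. Of 26 cytokines and chemokines 11 rose in spleen and 10 in lung, or 12 and 13 when adjusted over the list alone (camera adjusted p = 4.11e-06 and 2.82e-08; 0.0141 and 0.00733 with an estimated correlation). In lung 6 of 15 retention genes, 5 of 16 co-stimulation genes, 10 of 20 hypoxia and glycolysis genes and 7 of 12 regulatory T cell genes rose, and the sets were higher (0.00143, 5.25e-05, 7.94e-07 and 5.65e-05; 0.0467, 0.0123, 0.0467 and 0.04 with an estimated correlation). Markers of other cells moved with the tissue. In spleen 11 of 15 B and plasma cell genes rose (5.63e-10; 0.00627 with an estimated correlation). In lung 13 of 15 lung epithelial genes rose (5.67e-12; 0.0304 with an estimated correlation).

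The genes of largest rise in spleen were the chemokines CCL3L3 (at least 43.6-fold) and CXCL3 (307-fold, 95% counting interval 55 to 12200) and the inducible chaperones HSPA1B (8.84 ± 2.06), HSPA1A (7.66 ± 2.12) and HSPA6 (7.53 ± 2.20). CCL3L3 and the HSPA1A and HSPA1B pair have near-identical copies, so their reads are uncertain. Bounds are given where 1 group had 0 counts and set 3 counts over that group's libraries as the floor, and bounds and intervals cover counting error only. The genes of largest fall were ANGPTL7 (at least 108-fold) and C1QTNF7 (at least 64-fold), both secreted proteins, and the U4 small nuclear RNA RNU4-1 (448-fold, 79.4 to 17800), a near-identical copy of RNU4-2. They also included the imprinted RNA H19 (241-fold, 42.2 to 9610) and PRO1768 (-7.15 ± 1.06), an antisense transcript of FOXN3. It is uncertain because the counting strand is not given. Among the largest rises in lung were OLR1, a scavenger receptor of macrophages (at least 469-fold), APOC1, an apolipoprotein (at least 404-fold), and the lung epithelial genes SFTPA2 (at least 401-fold), SLPI (at least 120-fold) and KRT7 (at least 93.5-fold). The surfactant gene SFTPC was 1020-fold higher (183 to 40300). The largest falls in lung were the muscle creatine kinase CKM (at least 489-fold) and the U2 small nuclear RNA RNU2-2 (-6.77 ± 1.20). They included the antisense genes DISC2 (at least 64-fold), ZBTB20-AS2 (264-fold, 46.5 to 10500) and ITPK1-AS1 (157-fold, 42.6 to 1310), which are uncertain likewise, as is SFTPA2, a near-identical copy of SFTPA1. In total 2552 genes passed in spleen, 1516 higher and 1036 lower. In lung 2427 passed, 1297 higher and 1130 lower, a balance that turned with DESeq2's size factors within edgeR (1124 and 1258). The spleen count was 2380, 2222 and 445 without spleen CD69- replicates 1, 2 and 3 and 197, 2008 and 698 without blood replicates 1, 2 and 3. The lung count was 1068, 504 and 810 without lung CD69- replicates and 347, 1308 and 1186 without blood replicates 1, 2 and 3. Of the genes named, 7 of 17 in spleen and 13 of 19 in lung passed in each of the 6 fits without 1 library, with highest adjusted p-values of 0.335 (H19) and 0.13 (CKM), both without blood CD4 replicate 3.

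In CD8 cells the CD69- fractions of spleen and lung had more RGS1 (3.85 ± 0.84 and 3.91 ± 0.84), IL10 (3.25 ± 0.53 and 4.10 ± 0.53) and BATF (2.14 ± 0.43 and 2.11 ± 0.43) than blood. Spleen cells had more TNFRSF18 (4.66 ± 0.93) and JUN (5.13 ± 1.39), although JUN did not separate the libraries completely, and less CX3CR1 (-2.78 ± 0.52). Lung cells had more CCL3 (3.81 ± 0.80) and less TCF7 (-1.44 ± 0.30). Adjusted p-values ran from 0.00244 (IL10, lung) to 0.0463 (JUN). In lung 4 of 15 retention genes and 8 of 23 cytokines and chemokines rose, or 5 and 11 when adjusted over each list alone (0.00158 and 9.1e-06; both 0.0376 with an estimated correlation). In spleen 4 of 23 cytokines rose (4.4e-05; adjusted p = 0.0596 with an estimated correlation). B and plasma cell genes rose in spleen, 4 of 15 across all genes and 11 over the list alone (1.41e-10; 0.00712 with an estimated correlation), with CD79A at 3.29 ± 0.54. In lung 13 of 15 lung epithelial genes rose (4.28e-16; 0.0211 with an estimated correlation). The largest rises in spleen were HSPA1B (8.40 ± 1.91) and HSPA1A (7.31 ± 1.84), uncertain as copies, the chemokines CCL20 (7.69 ± 2.07) and CXCL2 (295-fold, 52.8 to 11700) and the integrin chain ITGAD (7.68 ± 1.17). The largest rises in lung were SFTPA2 (at least 1200-fold), CXCL3 (at least 473-fold), SFTPC (2780-fold, 499 to 110000), APOC1 (2030-fold, 365 to 80400) and the alveolar phosphate transporter SLC34A2 (at least 151-fold). The largest falls in spleen were the taste receptor TAS2R30 (at least 116-fold), the muscle gene XIRP1 (counting interval 79.5-fold to 1140-fold), the mucin MUC6 (-7.74 ± 0.91), RNU2-2 (-7.10 ± 1.31) and the orphan receptor GPR22 (160-fold, 54.2 to 783). In lung they were RNU2-2 (-7.16 ± 1.31), the 7SK RNA RN7SK (-7.05 ± 1.55), the U4 copies RNU4-2 (-6.63 ± 1.42) and RNU4-1 (-6.16 ± 1.30) and TAS2R30 (-6.12 ± 1.21). In total 846 genes passed in spleen, 342 higher and 504 lower, and 1043 in lung, 565 higher and 478 lower (464 and 503 with DESeq2's size factors within edgeR). The spleen count was 486, 130 and 284 without spleen CD69- replicates 1, 2 and 3 and 142, 381 and 233 without blood replicates 1, 2 and 3. The lung count was 554, 259 and 528 without lung CD69- replicates and 94, 282 and 412 without blood replicates 1, 2 and 3. Of the genes named, 5 of 17 in spleen and 5 of 15 in lung passed in each of the 6 fits without 1 library, with highest adjusted p-values of 0.262 (XIRP1, without blood CD8 replicate 3) and 0.112 (CXCL3, without blood CD8 replicate 1).

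The CD69+ fractions were set against blood in the same way, a comparison of the cells marked as resident with circulating memory cells. In CD4 cells RGS1 rose by 4.61 ± 0.82 in spleen and 6.17 ± 0.89 in lung, CXCR6 by 2.89 ± 0.69 and 5.51 ± 0.78 and ITGAE by 2.56 ± 0.48 and 3.45 ± 0.49. CXCL13 rose by 5.80 ± 1.38 and 5.70 ± 1.37 and the inhibitory receptor PDCD1 (PD-1) by 3.64 ± 0.64 and 4.24 ± 0.66. S1PR1 (-3.19 ± 0.50 and -2.32 ± 0.48), KLF3 (-2.25 ± 0.29 and -1.63 ± 0.29), FAM65B (-2.84 ± 0.41 and -2.92 ± 0.41) and CX3CR1 (-3.30 ± 0.85 and -3.61 ± 0.86) fell in both. In lung ITGA1 rose by 2.16 ± 0.72 and TCF7 fell by 2.93 ± 0.33. Adjusted p-values of these genes ran from 0.000353 (TCF7) to 0.0467 (ITGA1). Of 26 cytokines and chemokines 14 rose in spleen and 17 in lung, 18 and 22 when adjusted over the list alone (2.93e-10 and 4.37e-12; 0.00155 and 0.00172 with an estimated correlation). Of 12 follicular helper genes 6 rose in spleen (1.65e-05; 0.00495 with an estimated correlation), and in lung 6 rose and 3 fell (0.00901; 0.0479 with an estimated correlation). The list shares genes with other lists and holds the B cell gene POU2AF1, so its rise is not particular to follicular helper cells. In lung 9 of 15 retention genes, 7 of 16 co-stimulation genes, 13 of 23 feedback regulators and 13 of 20 hypoxia genes rose (1.71e-06, 2.82e-05, 8.33e-07 and 8.64e-07; 0.00809, 0.00809, 0.0366 and 0.0417 with an estimated correlation). In spleen 4 of 15 egress genes fell (0.00103; adjusted p = 0.0597 with an estimated correlation). B and plasma cell genes rose in spleen, 9 of 15 (2.11e-12; 0.00155 with an estimated correlation), and lung epithelial genes in lung, 13 of 15 (3.5e-10; 0.0366 with an estimated correlation). The largest rises in spleen were IL17A (at least 95.6-fold), CCL4L1 (at least 35-fold), SHISA2 (at least 26.2-fold), HSPA1B (8.39 ± 2.02) and IL1B (7.78 ± 1.99). CCL4L1 and HSPA1B are uncertain as near-identical copies. The largest falls in spleen were PRO1768 (-7.75 ± 1.10), TAS2R30 (268-fold, 73.3 to 2230), BTBD9-AS1 (313-fold, 55.2 to 12500), KCTD4 (247-fold, 43.3 to 9860) and ZBTB20-AS2 (141-fold, 38 to 1180). PRO1768, BTBD9-AS1 and ZBTB20-AS2 are antisense and uncertain. In lung SFTPA2 (at least 834-fold), OLR1 (at least 559-fold), APOC1 (at least 399-fold), SFTPC (3350-fold, 601 to 132000) and IL1A (at least 141-fold) rose most. MUC6 (727-fold, 200 to 6020), C1QTNF7 (249-fold, 43.3 to 9960), the muscle genes SYNPO2L (164-fold, 44.3 to 1380) and MYBPC3 (-6.63 ± 1.39) and RN7SK (-6.64 ± 1.44) fell most. In total 1611 genes passed in spleen, 777 higher and 834 lower, and 3212 in lung, 1827 higher and 1385 lower. The spleen count was 884, 304 and 837 without spleen CD69+ replicates 1, 2 and 3 and 266, 959 and 500 without blood replicates 1, 2 and 3. The lung count was 1759 without lung CD69+ replicate 2 and 919 and 2020 without blood replicates 1 and 3. Of the genes named, 11 of 19 in spleen and 16 of 21 in lung passed in each of the 6 fits without 1 library, with highest adjusted p-values of 0.12 (IL1B, without blood CD4 replicate 1) and 0.263 (SYNPO2L, without blood CD4 replicate 3).

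In CD8 cells RGS1 rose by 5.39 ± 0.90 in spleen and 5.92 ± 0.92 in lung, ITGAE by 3.18 ± 0.72 and 4.64 ± 0.77 and ITGA1 by 3.18 ± 0.90 and 4.93 ± 0.98. CXCR6 rose by 2.32 ± 0.66 and 3.24 ± 0.69, CXCL13 by 5.31 ± 1.32 and 6.09 ± 1.36 and PDCD1 by 2.06 ± 0.61 and 3.07 ± 0.64. PDCD1 did not separate the spleen libraries from blood completely. CX3CR1 (-7.16 ± 0.65 and -6.02 ± 0.63), FGFBP2 (-4.81 ± 0.95 and -4.42 ± 0.94) and S1PR1 (-2.81 ± 0.65 and -2.81 ± 0.65) fell in both. The same held for FAM65B (-2.38 ± 0.45 and -2.90 ± 0.46) and KLF3 (-1.86 ± 0.29 and -1.52 ± 0.29), and TCF7 fell in lung (-2.22 ± 0.31). Adjusted p-values ran from 0.000343 (CX3CR1, spleen) to 0.0477 (PDCD1, spleen). Of 15 retention genes 7 rose and 1 fell in spleen and 8 rose in lung (0.00335 and 3.43e-07; 0.0392 and 0.00468 with an estimated correlation). Of 23 cytokines and chemokines 10 and 12 rose, or 15 and 18 over the list alone (1.3e-08 and 1.63e-10; 0.00862 and 0.00498 with an estimated correlation). Follicular helper genes rose in spleen, 4 of 11 (4.5e-05; 0.00862 with an estimated correlation), as did B and plasma cell genes, 7 of 15 (8.96e-11; 0.00664 with an estimated correlation). In lung 5 of 15 egress genes fell (4.44e-05; 0.0462 with an estimated correlation). There 6 of 24 transcription factors, 5 of 16 co-stimulation genes, 8 of 23 feedback regulators and 12 of 15 lung epithelial genes rose (0.0132, 0.000443, 7.6e-08 and 5.22e-12; 0.0462, 0.0226, 0.0326 and 0.0151 with an estimated correlation), while 2 of the transcription factors fell. The largest rises in spleen were CXCL3 (at least 201-fold), CCL20 (10.44 ± 2.20), CCL3L3 (367-fold, 65.7 to 14500), IL17A (at least 50.8-fold) and HSPA1B (8.91 ± 1.95). In lung they were SFTPA2 (at least 608-fold), CXCL3 (at least 401-fold), the keratin KRT86 (at least 381-fold), SFTPC (1520-fold, 272 to 59900) and APOC1 (1570-fold, 281 to 62000). Apart from CX3CR1, the largest falls were SEMA5A (426-fold, 75.5 to 16900), the muscle gene NEBL (195-fold, 53 to 1620), PRO1768 (-6.87 ± 1.30) and FOXP1-IT1 (-6.82 ± 1.12) in spleen. In lung they were MUC6 (-7.25 ± 0.92), FOXP1-IT1 (137-fold, 46.4 to 669), TAS2R30 (132-fold, 35.9 to 1100) and the acetylcholine receptor chain CHRNG (93.7-fold, 25.4 to 782). CCL3L3, HSPA1B and SFTPA2 are uncertain as near-identical copies, and FOXP1-IT1 and PRO1768 because they lie within or against another gene. In total 1595 genes passed in spleen, 762 higher and 833 lower, and 2212 in lung, 1241 higher and 971 lower. The spleen count was 792 and 338 without spleen CD69+ replicates 2 and 3 and 374, 701 and 587 without blood replicates 1, 2 and 3. The lung count was 1149, 1000 and 1353 without lung CD69+ replicates and 560, 1059 and 1380 without blood replicates 1, 2 and 3. Of the genes named, 8 of 20 in spleen and 16 of 21 in lung passed in each of the 6 fits without 1 library, with highest adjusted p-values of 0.182 (PDCD1, without spleen CD8 CD69+ replicate 2) and 0.0851 (KRT86, without blood CD8 replicate 1).

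**Figure D3:**
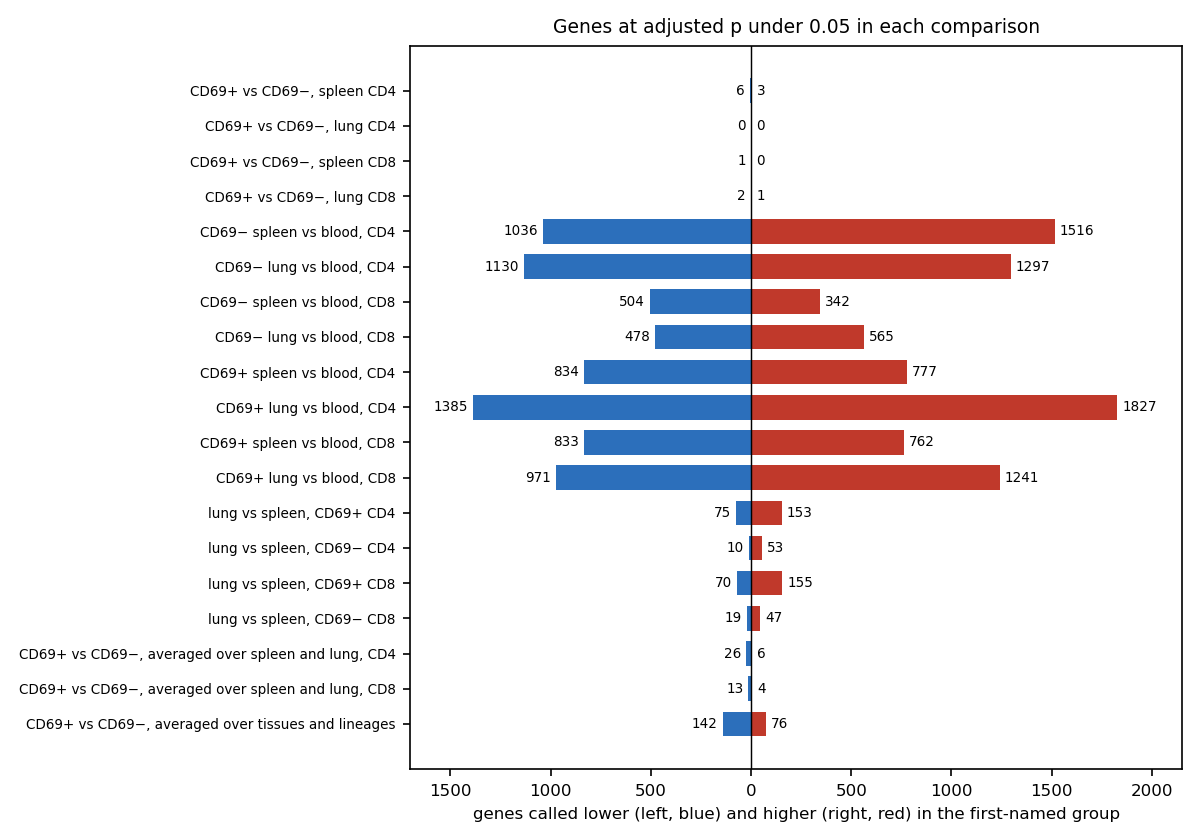
Number of genes called lower (left) and higher (right) at an adjusted p under 0.05 in the first-named group of each comparison, from edgeR's quasi-likelihood test on the libraries of each comparison's fit. Comparisons with blood reach 1827 higher and 1385 lower (CD69+ lung against blood, CD4), against 3 and 6 or fewer in the single-tissue CD69 comparisons, and the 3 comparisons of CD69 differences, with 0 calls, are not drawn.

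Lung and spleen were compared within each sorted fraction. In CD69+ CD4 cells, lung had more RBPJ, the DNA-binding partner of Notch (2.96 ± 0.38), the aryl hydrocarbon receptor AHR (1.48 ± 0.30), the MAPK phosphatase DUSP4 (3.18 ± 0.54) and the chemokine receptors CCR6 (2.90 ± 0.58) and CCR8 (3.67 ± 0.76). Higher too were the protease CTSH (2.52 ± 0.40), ITGB1 (2.00 ± 0.46) and PPARG, a lipid-sensing nuclear receptor also abundant in alveolar macrophages (4.63 ± 0.67). Lung epithelial and macrophage genes rose in the same libraries, so whether T cells carried the CTSH and PPARG rises is not known. Spleen had more TCF7 (-2.05 ± 0.32), the follicle-homing receptor CXCR5 (-3.58 ± 0.65) and the inhibitory receptor TIGIT (-2.33 ± 0.55). B and plasma cell genes were higher in spleen as well, so whether T cells carried the CXCR5 difference is not known. Of 15 retention genes 2 rose in lung and 6 when adjusted over the list alone (camera adjusted p = 1.5e-06; 0.0103 with an estimated correlation). The co-stimulation set was higher (0.00036; 0.0136 with an estimated correlation), with 3 of 16 genes higher over the list alone. In the same libraries 8 of 15 lung epithelial genes rose and 9 of 15 B and plasma cell genes fell (7.89e-17 and 2.81e-21; 0.0103 and 0.000293 with an estimated correlation). The macrophage receptor MARCO (4.57 ± 0.83) and the mast cell protease CPA3 (88-fold, 24.1 to 732) rose. The largest rises were SFTPC (10.85 ± 1.11), SFTPB (9.14 ± 1.25), the club cell secretory gene SCGB1A1 (1830-fold, 329 to 72400) and SFTPA1 (2340-fold, 802 to 11400) and SFTPA2 (9.85 ± 1.36), uncertain as copies of each other. Among the largest falls were the B lineage genes FCRLA (321-fold, 57.1 to 12700), FCRL5 (-5.91 ± 1.14) and PAX5 (-5.75 ± 1.09) and the noncoding KIAA0125 (now FAM30A; -5.14 ± 1.02). In CD69- CD4 cells lung had more PPARG (3.63 ± 0.66) and MARCO (4.68 ± 0.85). The co-stimulation and regulatory T cell sets were higher (3.25e-05 and 1.37e-05; 0.00718 and 0.0191 with an estimated correlation), with 4 of 16 and 2 of 12 genes higher over each list alone. There 6 of 15 lung epithelial genes rose and 5 of 15 B and plasma cell genes fell (9.58e-29 and 1.64e-26; 0.00203 and 0.000107 with an estimated correlation). The largest rises there were SFTPC (1310-fold, 361 to 10800), SFTPB (9.47 ± 1.29), COLEC12 (at least 86.5-fold), SFTPA2 (9.04 ± 1.39) and SLC34A2 (399-fold, 136 to 1940). Among the largest falls were the B lineage genes FCRLA (226-fold, 40.2 to 8970), FAM129C (-4.43 ± 0.84), MS4A1 (-3.66 ± 0.58) and CD22 (-2.86 ± 0.55). In total 228 genes passed in CD69+ cells, 153 higher and 75 lower, and 63 in CD69- cells, 53 higher and 10 lower. The CD69+ count was 58, 84 and 103 without spleen replicates 1, 2 and 3 and 134, 82 and 149 without lung replicates. The CD69- count was 12, 3 and 20 and 32, 19 and 25 in the same order. Without the 4 spleen libraries of low FOS the counts were 71 and 4. Of the genes named, 9 of 22 in CD69+ and 1 of 11 in CD69- cells passed in each of the 6 fits without 1 library, with highest adjusted p-values of 0.2 (TIGIT) and 0.212 (COLEC12), both without replicate 1 of the spleen group.

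In CD69+ CD8 cells, lung had more ZNF683 (4.57 ± 0.64), CTLA4 (3.08 ± 0.50), AHR (2.13 ± 0.36), the activating receptor CD226 (2.08 ± 0.41), RBPJ (1.87 ± 0.35), ITGB1 (1.95 ± 0.35) and PPARG (3.97 ± 0.77) than spleen. It had less of the gut-homing receptor CCR9 (-4.19 ± 0.78), CXCR5 (-2.57 ± 0.54) and TCF7 (-1.41 ± 0.30), at adjusted p-values of 0.00624 to 0.038. B and plasma cell genes were lower in lung here too, so the CXCR5 difference cannot be assigned to T cells. Of 15 retention genes 1 rose and 2 when adjusted over the list alone (0.000486; 0.0166 with an estimated correlation). Lung epithelial genes rose, 8 of 15 in CD69+ and 7 of 15 in CD69- cells (1.34e-21 and 7.88e-32; 0.00224 and 0.000561 with an estimated correlation). B and plasma cell genes fell, 5 of 15 in each (1.38e-17 and 1.7e-27; 0.00224 and 0.000152 with an estimated correlation). CPA3 was 155-fold (42.3 to 1290) and 178-fold (31.5 to 7070) higher in lung, and PPARG rose by 4.58 ± 0.81 in CD69- cells. Among the largest rises in CD69+ cells were SFTPA2 (1480-fold, 506 to 7180), SFTPC (9.57 ± 1.08), SFTPB (9.14 ± 0.94), the collagen-processing PCOLCE2 (at least 121-fold) and the epithelial receptor GPRC5A (at least 95.6-fold). Among the largest falls were the B cell genes FCRLA (at least 58.7-fold), CR2 (62.8-fold, 21.3 to 306) and POU2AF1 (-5.42 ± 0.74) and the noncoding KIAA0125 (76.1-fold, 25.8 to 371). In CD69- cells the largest rises were SCGB1A1 (2770-fold, 497 to 109000), SFTPA2 (2510-fold, 859 to 12200), the macrophage receptor TREM2 (at least 226-fold), SFTPC (1940-fold, 663 to 9410) and SFTPB (1630-fold, 559 to 7920). Among the largest falls were POU2AF1 (-4.94 ± 0.69), ITGAD (-4.69 ± 0.94), CD79A (-4.38 ± 0.56) and BANK1 (-4.34 ± 0.84). In total 225 genes passed in CD69+ cells, 155 higher and 70 lower, and 66 in CD69- cells, 47 higher and 19 lower. The CD69+ count was 32, 44 and 95 without spleen replicates 1, 2 and 3 and 57, 105 and 62 without lung replicates. The CD69- count was 14, 15 and 15 without spleen replicates and 23 without lung replicate 2. Without the 4 spleen libraries of low FOS the counts were 49 and 15. Of the genes named, 8 of 20 in CD69+ and 5 of 11 in CD69- cells passed in each of the 6 fits without 1 library, with highest adjusted p-values of 0.166 (KIAA0125) and 0.232 (SCGB1A1), both without replicate 1 of the spleen group.

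**Figure D4:**
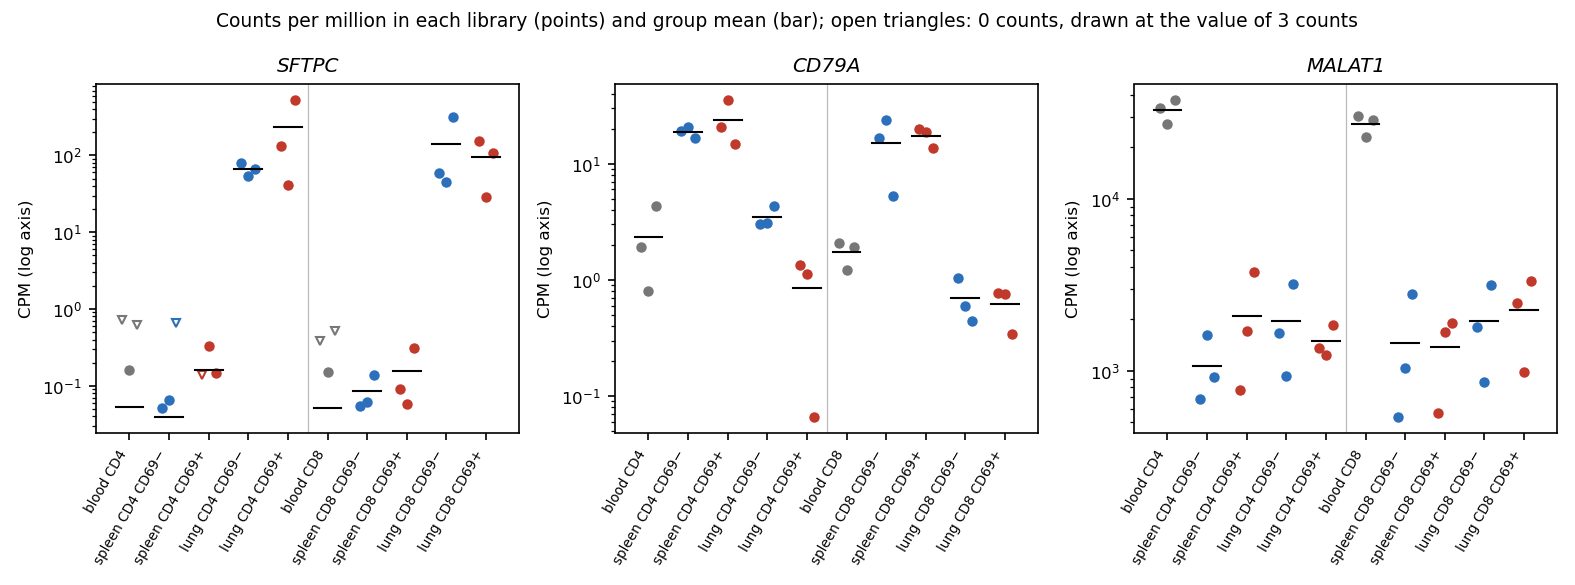
CPM (log axis) of SFTPC, CD79A and MALAT1 in each of the 30 libraries (points), with the mean of each group of 3 (bars, counting 0 as 0); open triangles stand for 0 counts and are drawn at the level of 3 counts. SFTPC lies between 28.7 and 521 CPM in lung and at or under 0.329 CPM elsewhere, CD79A between 5.27 and 35.1 CPM in spleen and at or under 4.35 CPM elsewhere, and MALAT1 between 22800 and 37300 CPM in blood and at or under 3740 CPM in tissue.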

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

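The tests of the 3 patterns weighed here were chosen after the results were seen. What other splits of the libraries would show was written down after the results for the single-tissue CD69 differences and for the comparisons with blood and between tissues, and before the splits were seen for the rest. In CD8 cells a test of the difference itself set lung apart from spleen. The retention and adhesion genes and the residency and effector transcription factors had a more positive CD69 difference in lung. Their camera adjusted p was 0.0213 and 0.0126 with an estimated correlation over 15 and 24 genes, with medians of 0.47 and 0.38 on the log2 scale. By edgeR 0 single genes passed, with 148 at an unadjusted p under 0.05, fewer than the 788 of evenly spread p-values. Unmodelled donors can lower that count. DESeq2 gave 1 call. The camera values were 0.0434 and 0.00968 without the 2 shallow tissue libraries and 0.0596 for both without the 4 spleen libraries of low FOS.

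The first pattern is that CD69 RNA did not fully separate cells sorted on the CD69 protein, although its group means were higher in CD69+ cells in 4 of 4 pairs. Exchanged gate labels are argued against by S1PR1, whose CD69+ libraries lay under all CD69- libraries in 4 of 4 pairs. Leaving out the 4 spleen libraries of low FOS left the averaged CD69 difference at 0.90 ± 0.37 against 0.89 ± 0.58 (adjusted p = 0.45 against 0.887; 0.45 to 1 over the alternatives), so those libraries did not mask a larger fold. A smaller difference than these libraries can resolve stays open, as does one that only a model of donors would show, and so does regulation of CD69 after transcription, for which no test was run.

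The second pattern is the higher level of the nuclear RNA MALAT1 in blood. No list of nuclear RNAs was tested. The 7SK RNA RN7SK also lay higher in blood, at 88.9 to 744 CPM against 0.865 to 97.3 CPM in tissue, with overlapping ranges. RNU2-2, RNU4-1, RNU4-2 and RN7SK were among the largest falls against blood, but they were picked for their size and do not test a cause. Lower depth of the blood libraries is argued against, since the 4 tissue libraries with totals no higher than the deepest blood library reached at most 3740 CPM of MALAT1, against at least 22800 CPM in blood. A difference in RNA selection or library preparation might also raise histone transcripts, which lack poly-A tails. Their median change in the 4 comparisons of CD69- tissue with blood ran from -1.85 to 0.658 on the log2 scale, so it did not settle the question, and the cause stays open: handling and site differed between blood and tissue together, and whether preparation and donors differed too is not known.

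The third pattern is the presence of transcripts of other cell types in sorted T cells. RNA or cells carried over from the surrounding tissue could account for it and were not tested apart from the pattern: in 4 of 4 comparisons of lung with spleen the lung epithelial list was higher in lung and the B and plasma cell list higher in spleen, which is the pattern itself. A gate on CD3 should remove such cells, and 2 of 15 epithelial and 10 of 15 B and plasma cell list genes reached 1 CPM in blood, where SFTPB reached 1.20 CPM and CD79A 4.35 CPM. The levels were 28.7 to 521 CPM of SFTPC in lung and 5.27 to 35.1 CPM of CD79A in spleen. Of the macrophage and monocyte list, 15 of 20 genes averaged at least 1 CPM in blood. LYZ of that list lay at 139 to 892 CPM in blood, 4.9 to 368 CPM in spleen and 78.4 to 1370 CPM in lung. MARCO reached 460 CPM in lung, against at most 7.97 CPM in spleen and blood. Blood was thus not free of such transcripts, and whether T cells carried the rises of genes shared with other cells was not tested. Libraries exchanged between lung and another tissue are argued against by SFTPC at no more than 0.329 CPM in any spleen or blood library, while RNA released during digestion and whole cells that passed the gate stay open.

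Other splits of the same libraries were counted. For single-tissue CD69 differences and for the comparisons with blood and between tissues, 10 splits are too few for a share under 0.05. For CD69 the real counts were 9, 0, 1 and 3 in spleen CD4, lung CD4, spleen CD8 and lung CD8 cells, the highest other counts 1, 0, 3 and 258, and 1, 10, 3 and 2 of the 10 splits gave as many. A split of the lung CD8 libraries other than the gate gave 258 calls, and what sets its libraries apart was not tested. Against blood the real counts of CD69- cells were 2552, 2427, 846 and 1043 and of CD69+ cells 1611, 3212, 1595 and 2212, in spleen CD4, lung CD4, spleen CD8 and lung CD8 cells, and for lung against spleen 228, 63, 225 and 66 in CD69+ CD4, CD69- CD4, CD69+ CD8 and CD69- CD8 cells. In these 12 comparisons the highest other count was 0, except 1 for CD69+ spleen CD8 cells, and 1 of 10 splits, the real one, gave as many.

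With 100 drawn regroupings, the average over tissues and lineages (218 calls) was reached by 1, the real one, with 57 as the highest other. The averages of CD4 (32) and CD8 (17) were reached by 2 and 3, with 53 and 1771 as the highest others. These shares lie under 0.05, but the averages were chosen after the single-tissue results were seen. The regroupings also treat libraries that may share a donor as exchangeable, so a random assignment of labels is not excluded. What sets the regrouping of CD8 libraries with 1771 calls apart was not tested either. The genes shared in CD8 cells (1) and those also differing from blood (1) were reached by 1 of 100, with 0 as the highest other. Those differing from blood are drawn from the shared genes, so their count is not a separate result. The comparisons with 0 calls, which were the lung minus spleen differences in CD4 and CD8 cells, CD8 minus CD4, and genes shared in CD4 cells, were matched by 100 of 100, with highest others of 53, 769, 143 and 0. At an unadjusted p under 0.05, 126 genes moved the same way in both tissues in CD4 and 104 in CD8 cells, and 15 of 100 regroupings gave as many in each lineage, with highest values of 379 and 793.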

How the results depend on the processing

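Leaving out the 4 spleen libraries of low FOS, leaving out the 2 shallow tissue libraries, and every averaged difference were chosen after the results were seen, and the other alternatives were fixed in advance. No paired analysis was run, because the columns carry no donor and the replicate numbers follow the order of deposit. The planned donor block was therefore not run either. Some values did track these numbers. FOS lay at 11.5 to 14.3 CPM in replicate 1 of the 4 spleen groups, against 2030 to 4070 CPM in replicates 2 and 3. Whether the numbers mark donors is not known, so spread between donors may add to the error of these tests. No named gene reversed its direction under any setting. Of 292 gene and comparison pairs named, 288 kept their side of the threshold with DESeq2's size factors within edgeR, 291 with no filter, 289 with 2 surrogate variables, 284 with DESeq2 and 243 of 256 in 1 fit of all 30 libraries, against 237 without the shallow libraries and 217 without the low FOS libraries, where groups hold fewer samples. With DESeq2's size factors within edgeR every count stayed within 1.5 times its value, and the scaling moved the median of all genes by at most 0.075 on the log2 scale. All 218 genes of the average over tissues and lineages kept their sign with DESeq2, with its size factors within edgeR, with no filter, with surrogate variables, and without the shallow or the low FOS libraries. Of them 217 were called by DESeq2, 218 with surrogate variables, 160 without the shallow libraries and 155 without the low FOS libraries. Apart from fewer samples in some settings, the cause of these shifts was not tested. In simulated counts edgeR found 0% of 2-fold changes in spleen CD4 cells, so changes of that size there would be missed.

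DESeq2 called 91, 26, 30 and 85 genes for CD69+ against CD69- in spleen CD4, lung CD4, spleen CD8 and lung CD8 cells (9, 0, 1 and 3 by edgeR). It called 11 and 1 for lung minus spleen in CD4 and CD8 cells and 1 for CD8 minus CD4 (0 each by edgeR), and 9 shared genes in CD4, 11 in CD8 and, over both lineages, 19 also differing from blood (0, 1 and 1). Against blood it called 1817 and 2100 in CD69- spleen and lung CD8 cells (846 and 1043) and 2779 and 2615 in CD69+ spleen CD4 and CD8 cells (1611 and 1595). Between lung and spleen it called 862, 255, 965 and 384 in CD69+ CD4, CD69- CD4, CD69+ CD8 and CD69- CD8 cells (228, 63, 225 and 66), and for the averages 138 in CD4, 122 in CD8 and 389 over both (32, 17 and 218).

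With 2 surrogate variables the counts were 35 for spleen CD4, 0 for spleen CD8 and 29 for lung CD8 cells, 3637 and 3504 for CD69- spleen and lung CD8 cells against blood, and 3556, 4599 and 4878 for CD69+ spleen CD4, spleen CD8 and lung CD8 cells against blood. They were 804, 134, 1745 and 546 for lung against spleen in the order above, 103, 81 and 468 for the averages, and 0 and 0 for the genes shared in CD8 cells and those also differing from blood. In 1 fit of all 30 libraries the counts were 15, 1, 0 and 11 for CD69 in spleen CD4, lung CD4, spleen CD8 and lung CD8 cells, 2597 for CD69+ spleen CD4 cells against blood, 410 and 117 for lung against spleen in CD69+ CD4 and CD69- CD8 cells, 44 for the CD8 average, and 1 and 0 shared genes in CD4 and CD8 cells. With no filter they were 15 for spleen CD4, 2 for spleen CD8 and 28 for the CD8 average.

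Without the low FOS libraries edgeR gave 0 calls for spleen CD4, 0 for spleen CD8 and 0 for lung CD8 cells, 71, 4, 49 and 15 for lung against spleen in the order above, 21 for the CD4 average, and 0 and 0 for the genes shared in CD8 cells and those also differing from blood. Without the shallow libraries it gave 16, 0 and 0 for spleen CD4, spleen CD8 and lung CD8 cells, 445 and 2553 for CD69- and CD69+ spleen CD4 cells and 671 and 1149 for CD69- and CD69+ lung CD8 cells against blood, 356, 20, 57 and 39 for lung against spleen, 1 for the CD8 average, and 0 and 0 for the same shared genes. Of the 494 list tests of the comparisons planned in advance, 227 passed with the preset correlation and 65 with an estimated one.

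Leaving out 1 library gave 0 to 16, 0 to 0, 0 to 3 and 0 to 5 calls for CD69 in spleen CD4, lung CD4, spleen CD8 and lung CD8 cells and 0 for the 3 differences between tissues or lineages. It gave 197 to 2380, 347 to 1308, 130 to 486 and 94 to 554 for CD69- spleen CD4, lung CD4, spleen CD8 and lung CD8 cells against blood, and 266 to 959, 919 to 2654, 338 to 1334 and 560 to 1380 for the CD69+ cells in the same order. For lung against spleen it gave 58 to 149, 3 to 32, 32 to 105 and 14 to 68, for the averages 12 to 36 in CD4, 1 to 39 in CD8 and 145 to 229 over both, and for shared genes 0 in CD4, 0 to 1 in CD8 and 0 to 1 also differing from blood. Every comparison with blood lost calls whichever of its libraries was left out, where 1 group keeps 2 libraries.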

Other observations

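The classes of genes described here were looked up after the results were seen. Genes of ribosomal proteins stood higher in tissue than in blood. In CD69- cells their median change was 2.89 in spleen CD4, 2.07 in lung CD4, 1.73 in spleen CD8 and 1.39 in lung CD8 cells on the log2 scale, and 71 of 83, 36 of 83, 45 of 82 and 29 of 82 rose with 0 falling. In CD69+ cells the medians were 1.94, 1.40, 1.70 and 1.44 in the same order, with 15, 14, 53 and 43 rising and 0 falling. The direction held with DESeq2 and with its size factors within edgeR, where the medians ran from 1.35 to 2.88. RPS19, for example, lay between 1300 and 7060 CPM in spleen, 555 and 2200 CPM in lung and 89.4 and 481 CPM in blood. Processed pseudogenes of these genes are many, so reads can be split between copies.

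Immediate early and heat shock lists, which respond to tissue dissociation in other settings, were higher in tissue than in blood with the preset correlation only. Replicate 1 of the 4 spleen groups ran the other way for FOS, at 11.5 to 14.3 CPM against 46 to 287 CPM in the 6 blood libraries. The adjusted p-values of the 2 lists with an estimated correlation ran from 0.133 to 0.577 and from 0.39 to 0.577 over the 8 comparisons with blood. HSPA1A, uncertain as a near-identical copy of HSPA1B, lay between 22.3 and 5080 CPM in spleen, 54.2 and 3550 CPM in lung and 7.67 and 20.5 CPM in blood.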
